A study of Drosophila melanogaster with 3 samples.

How the data were processed

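Chromatin immunoprecipitation followed by sequencing (ChIP-seq) with an antibody against GFP was carried out on whole wandering L3 larvae (the last larval stage) of Drosophila melanogaster, males and females pooled, from a transgenic line that carries GFP fused to Rel, per the labels. Rel (Relish) is the NF-κB family transcription factor at the end of the IMD immune signalling pathway. The 3 samples are 3 biological replicates of 1 group, numbered as in the labels, with fragments of 200 to 800 bp. No second condition was present, so no comparison between conditions was made. A control experiment is named in the labels and was not analysed here.

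Per the file headers, the authors called peaks separately in each replicate and on the alignments of all 3 replicates together, each time with a control library, on genome build dm6, and deposited 30000 peaks per list. An optimal list, kept by the irreproducible discovery rate (IDR) between replicates, was derived by the authors from these lists per the file headers, and holds 9419 peaks. The aligner, the peak caller and the IDR threshold are not given in the sources used here. Each peak's height is the signal value deposited by the authors' peak caller, on a scale set by the caller and the library. Each peak also has a −log10 q-value as deposited by the authors, with 11473 to 14513 peaks per replicate tied at the highest value. The optimal list holds a single −log10 q-value, 4.43, so peaks were ranked by signal. All 9419 optimal peaks were found in the pooled list, where they were the 9419 peaks of highest signal. Sequencing depth is unknown, because the lists hold no read counts, so signal values were used to rank peaks within a list, and between replicates only as correlations across peaks and as the relative signal defined below.

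Chromosome arm lengths of the RefSeq release 6 sequence and the Ensembl annotation were checked against the peaks, all of which lay inside the arms. Coordinates are 1-based and refer to dm6. Summits were compared by distance, and summits within 100 bp of each other were counted as shared. The top 9419 peaks of each replicate were used for overlap. Relative signal is a replicate's signal at the matching peak divided by the median over its matched optimal peaks, and is given as mean ± SD over 3 replicates. As controls for peak overlap and position, 100 seeded random placements per chromosome arm were drawn, so 0.0099 was the smallest permutation p possible for them. For gene lists, 10000 random lists matched on TSS number were drawn, which allow smaller permutation p-values. A promoter is the sequence within 500 bp of an annotated transcription start site (TSS), and a gene was counted as having a peak where an optimal summit lay within 1000 bp of any of its TSSs. Where a gene had several such peaks, its rank, signal and motif match are those of the peak of highest signal. The background was the other protein-coding genes out of 13945.

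The 17 gene lists, the motifs, the main tests and the rule for named genes were fixed before the data were examined, as were the alternatives other than those said to be added later. The rule takes the 20 peaks of highest signal, the 8 genes of highest signal in each of the antimicrobial peptide, peptidoglycan recognition protein and IMD lists, Rel itself, and up to 3 genes of each other list. A gene that the rule would name is not reported here. Lists were compared with other genes by a two-sided Fisher exact test with Benjamini-Hochberg adjustment over the 17 lists, at a threshold of 0.05. Names were matched by symbol or older name. BaraA was not matched. The testis gene name don occurred only as an older name of svp, a nuclear receptor gene, and was left out of the testis list after the list's result had been seen. Both counts are reported.

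Motif matches on either strand were counted in 201 bp windows centred on summits and in 1 window per peak 1000 bp away, on 9214 pairs, with an exact two-sided McNemar test and Benjamini-Hochberg adjustment over 10 motifs. The κB consensus was GGGRNNYYCC. Percentages of single lists carry exact Clopper-Pearson 95% intervals, which cover counting error only. Genes and peaks are not biological replicates, so these p-values describe this peak list. Bootstrap intervals of ratios used 1000 resamples of peaks and were added after the ratios had been seen, so that a bound counted as passed only where the whole interval lay beyond it. The functions were tested on simulated data. Of 500 simulated lists of 20 genes with planted peaks, 98.6% passed an unadjusted threshold of 0.05, against 3.80% of random lists. The planted difference was large, and the simulated genes were evenly spaced with a single TSS each. These rates need not hold for smaller differences or lists, clustered genes or genes with several TSSs. For motifs, 100% of 200 planted sets and 5.50% of unplanted sets passed. Alternatives covered summit distances, TSS windows, backgrounds, motif forms and windows, the top 50% of peaks by signal, and leaving out each replicate in turn. For replicate overlap, pairwise sharing and correlation, leaving out a replicate used the other replicates alone. For all other tests it kept the optimal peaks with a shared summit among the top peaks of both other replicates (6568 to 7023 peaks). The optimal list itself was still derived from all replicates. Such a set is therefore a stricter filter, and the effect of removing a replicate was not tested. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.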

Results

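ChIP-seq peaks of GFP-tagged Rel were analysed from 3 biological replicates of whole wandering L3 larvae. The optimal list held 9419 summits in 8681 intervals with a median peak width of 390 bp, covering 3.81 Mb. The depth of each library is unknown. Signal in the optimal list ran from 191 to 20515, with a median of 383.

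The first question was how far the 3 replicates shared the same peaks. Of the optimal summits, 84.2% ± 2.10 (SD, n = 3) had a summit within 100 bp among the top 9419 peaks of a replicate. The values were 83.2% in replicate 1, 82.8% in replicate 2 and 86.6% in replicate 3. Random placement gave 1.42% on average and at most 1.87%. A matching peak was found in all 3 replicates for 6060 summits (64.3%), in 2 for 2306, in 1 for 1001 and in none for 52. Because the optimal list was derived from the same replicates, this overlap is not independent of it. Between replicates, 73.9% ± 2.80 (SD, n = 3 pairs) of the top peaks were shared. Spearman's rho of signal across peaks, which are not independent replicates, was 0.70 for replicates 1 and 2, 0.83 for replicates 1 and 3, and 0.77 for replicates 2 and 3.

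The peaks of highest signal lay at genes of several functions. The strongest was 93 bp from the TSS of CG42788 (3R:15131460-15132259, relative signal 50.3 ± 14.3, SD, n = 3). It was followed by AGO2, the Argonaute protein of small interfering RNA silencing (3L:15553685-15555053, 50.1 ± 8.10), Rabex-5, an exchange factor for Rab5 (3L:1295389-1296365, 47.8 ± 13.1), TTLL4A (46.3 ± 13.6) and CG17272. The SDs of the first 4 are large against the gaps between them, so their order is not resolved. Ranks 6 to 8 were an intronic peak of eRF1, the translation release factor, and promoter peaks of CG45045 and Charon. PGRP-LF, a peptidoglycan recognition protein, was at rank 9 (3L:9348960-9350260, 35.2 ± 0.55) and pirk, a negative regulator of the IMD pathway, at rank 12 (2R:21659870-21664988, 31.6 ± 1.30). CG17754 and eIF4A, a translation initiation factor, were at ranks 10 and 11. Pp2C1 was the nearest gene to rank 13, and rank 14 lay in an intron of upd3, a cytokine ligand of the JAK-STAT pathway, 5300 bp from its nearest TSS (X:18282000-18282989, 29.5 ± 6.37). CG9331, hry, tRNA:Lys-CTT-1-1, CG4911, CG46385 and pst were nearest to ranks 15 to 20. Of these 20 peaks, 14 were at promoters and 8 had a κB match within 100 bp of the summit.

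The position of peaks in the annotation was compared with random positions. At promoters lay 4761 of 9419 summits (50.5%), against 13.6% of random positions, a 3.71-fold excess (one-sided permutation p = 0.0099, the smallest that 100 draws can give). Coding sequence held 1.38% of summits against 13.7% of random positions, intergenic sequence 9.35% against 27.4%, introns 35.2% against 39.3%, and 3′ UTRs 1.75% against 4.40%. Each of these was below all 100 draws (permutation p = 0.0099, again the smallest possible). Of these, introns fell least, to 0.896 of the random share, against 0.341 for intergenic sequence. At 5′ UTRs lay 1.05% of summits against 0.765% of random positions, above all 100 draws. Each summit had 1 class and promoter came first, so the promoter excess lowers the other shares by construction. Shares among summits outside promoters were not tested, so the intron value does not show that these summits avoid introns.

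**Figure D1:**
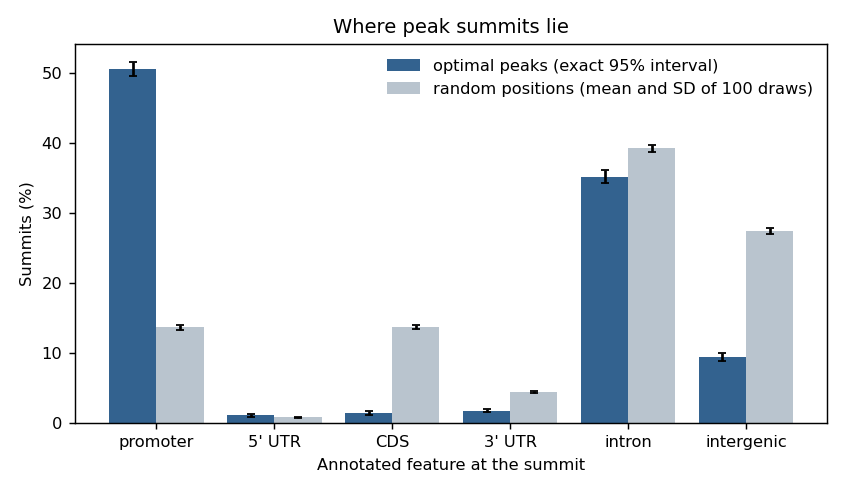
Percent of summits (y axis) by annotated feature (x axis), for optimal peaks with exact 95% intervals and for random positions with the mean and SD of 100 draws. Promoters hold 50.5% of summits and 13.6% of random positions.

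The share of genes with a peak was compared between each of 17 gene lists and other protein-coding genes. Of 27 antimicrobial peptide genes, 19 had a peak (70.4%, 95% interval 49.8 to 86.2), against 37.9% of other protein-coding genes (Fisher exact adjusted p = 0.00285). The 8 of highest signal were DptB (rank 87, relative signal 14.4 ± 3.10, SD, n = 3), edin (rank 119, 12.6 ± 3.05), AttC (rank 317), Mtk (rank 334), BomS3 (rank 504), AttA and Dro, which share the peak at rank 520, and CecC (rank 853). DptB encodes Diptericin B, AttC and AttA attacins, Mtk Metchnikowin and CecC a cecropin. The DptB summit was 94 bp from its TSS (2R:18866981-18867644).

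Of 13 peptidoglycan recognition protein genes, 10 had a peak (76.9%, Fisher exact adjusted p = 0.0132). All 10 peaks, the strongest of each gene, were in the top 25% of the list by signal, with a median rank of 326.5. After PGRP-LF came PGRP-LB (rank 38, 21.4 ± 1.67, SD, n = 3), an amidase, then PGRP-SA (rank 169), PGRP-SD (rank 179), PGRP-SB1 (rank 310), PGRP-LC (rank 343), the receptor of the IMD pathway, PGRP-SC2 (rank 405) and PGRP-SC1b (rank 788). Of 19 IMD pathway genes, 14 had a peak (73.7%, Fisher exact adjusted p = 0.00666). After pirk these were led by Tab2 (rank 80, 14.8 ± 2.43), key, the IKK gamma subunit (13.4 ± 3.23), imd, the adaptor (rank 196, 9.95 ± 2.41), scny (rank 511), trbd (rank 639), POSH (rank 955) and eff (rank 1647). Rel itself (3R:9044183-9047977) had no optimal peak within 1000 bp of a TSS, and 0 peaks of any replicate list lay in the gene or within 1000 bp of it. Against random lists matched on the number of TSSs, the call was lost for peptidoglycan recognition proteins (31.7 points, adjusted p = 0.0582, permutation) and IMD genes (25.1 points, adjusted p = 0.0640, permutation). It was also lost for peptidoglycan recognition proteins when only the first gene of each locus was counted, an alternative added after seeing the data (24.6 points, Fisher exact adjusted p = 0.216).

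For κB matches, only the strongest peak of each gene was counted, so weaker peaks of the same genes are left out. Sequence matching the κB consensus lay under 3 of 17 such peaks of antimicrobial peptide genes, 2 of 10 of peptidoglycan recognition protein genes and 2 of 14 of IMD genes. The other counted peaks, among them those of PGRP-LF, PGRP-LB, DptB, edin and imd, had no match to this consensus within 100 bp of the summit. Over all optimal peaks a relaxed form, GGGRNNYYYY, was present at 20.7% of summits and 8.29% of flanks. No list was tested for its share of matches, and the 6 peaks of chemoreceptor genes, a list with few peaks, included 4 with a match. In the pirk promoter GGGGAACTCC (2R:21662155-21662164) was 5 bp from the summit, and at key GGGAATTCCC (2R:24787109-24787118) was 21 bp away. PGRP-SA had GGGAGTCCCC (X:11561846-11561855) at 9 bp and PGRP-SD GGGGCACTCC (3L:7651124-7651133) at 41 bp. Among antimicrobial peptide genes, AttC had GGGAAGCCCC (2R:13393649-13393658) at 78 bp, Mtk GGGAAGTCCC (2R:15408662-15408671) at 42 bp and BomS3, on the minus strand, GGGATTCTCC (2R:18388004-18388013) at 50 bp. All 7 matched peaks were within 500 bp of a TSS.

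Other signalling lists were compared in the same way. Toll pathway genes had a peak in 14 of 18 cases (77.8%, Fisher exact adjusted p = 0.00285), led by cact, the IκB inhibitor (rank 250), GNBP3 (rank 390) and Pli (rank 736). Within 5000 bp the Toll difference fell from 39.9 to 25.1 points (Fisher exact adjusted p = 0.0496). Ecdysone response genes had a peak in 16 of 20 cases (Fisher exact adjusted p = 0.000946), led by br (rank 122), ImpE3 (rank 417) and Eip74EF (rank 707). The ecdysone call was lost against random lists matched on TSS number (23.9 points, adjusted p = 0.0602, permutation). JNK pathway genes had a peak in 9 of 13 cases (69.2%) and did not pass (Fisher exact adjusted p = 0.0643), with kay and Jra, which encode the AP-1 subunits Fos and Jun, at ranks 239 and 243 and puc at rank 480. The JNK difference of 31.3 points passed with TSSs within 500 bp (35.8 points, Fisher exact adjusted p = 0.0218). It was 15.4 points without replicate 1 and 16.5 without replicate 3, in the smaller sets of 6895 and 6568 optimal peaks matched in both other replicates. Neither passed, nor did the list within 5000 bp (69.2% against 58.2%, Fisher exact adjusted p = 0.748). JAK-STAT pathway genes had a peak in 6 of 16 cases (Fisher exact adjusted p = 1), among them Tep4 (rank 61), Stat92E (rank 174) and Tep2 (rank 364). The intronic peak of upd3 at rank 14 is too far from its TSS to count here. By nearest TSS the list had 8 of 16 genes with a peak, and the difference went from -0.42 to 15.6 points without passing (Fisher exact adjusted p = 0.239). Without replicate 1 it was -5.82 points and without replicate 3 -4.71, with 4 of 16 genes in both.

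Among lists of tissues and general functions, ribosomal protein genes had a peak most often, in 71 of 88 cases (80.7%, Fisher exact adjusted p = 2.1e-15). Within 5000 bp the difference fell from 43.0 to 24.9 points (83.0% against 58.1%). Members with a peak included RpL12 (rank 755) and RpL8 (rank 854, a peak shared with msn), and 2 of the 71 peaks had a κB match. Larval fat body genes (11 of 17, adjusted p = 0.0643) and heat shock genes (11 of 18, adjusted p = 0.0735) did not pass the Fisher exact test. Their strongest members were Pepck1 (rank 488), Lpin (rank 626) and Glyp (rank 1043), and Hsp27 (rank 526), Hsp83 (rank 1159) and Hsc70-5 (rank 1358). Both passed with TSSs within 500 bp (31.2 points, adjusted p = 0.0158, and 27.7 points, adjusted p = 0.0304, Fisher exact). The heat shock difference of 23.2 points did not pass within 5000 bp (8.45 points, Fisher exact adjusted p = 0.748) and was 2.52 points without replicate 1 (6 of 18, Fisher exact adjusted p = 0.802). That set was smaller, with 6895 of 9419 peaks, and 30.8% of other genes had a peak in it. The fat body list also passed without each replicate in turn, from 28.0 to 29.1 points, but not within 5000 bp (18.3 points, Fisher exact adjusted p = 0.207) or against random lists matched on TSS number (22.5 points, adjusted p = 0.118, permutation).

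Hemocyte genes (6 of 16, led by srp, crq and Fer1HCH), muscle genes (4 of 16, led by Mef2, Tm1 and Mlp60A), neuronal genes (2 of 15, elav and Syx1A) and digestive genes (5 of 21, led by Jon65Ai, Npc2f and cad) did not differ from other genes past the threshold. Hemocyte genes had 3 of 16 without replicate 1 and without replicate 2 (-12.1 and -12.0 points against -0.42), and the muscle difference of -12.9 points was -4.71 without replicate 3. The digestive difference went from -14.1 to -7.01 points without replicate 1, to -1.06 by nearest TSS and to 3.72 with loci counted once. None of these passed. With loci counted once, a locus had a peak where any of its genes had one, yet was compared with single genes. A locus of several genes has more chances of a peak, so such differences are not like for like. Muscle and neuronal genes had fewer peaks than random lists matched on TSS number (-31.7 points, adjusted p = 0.0268, and -42.2 points, adjusted p = 0.00510, permutation). Salivary gland glue genes had a peak in 0 of 21 cases (95% interval up to 16.1%, Fisher exact adjusted p = 0.000303), but they form 5 loci. With loci counted once the call was lost at an unchanged difference of -38.0 points (0 of 5, Fisher exact adjusted p = 0.215). As 0 of 5 is the lowest count possible, 5 loci are too few for a lower share to pass. Of 19 testis genes, 1 had a peak, Mst87F (Fisher exact adjusted p = 0.00433). With the doubtful match of don to svp kept, the testis difference was -28.0 points (Fisher exact adjusted p = 0.0183), and with the first gene of each locus alone, added after seeing the data, it was -30.3 points and did not pass (Fisher exact adjusted p = 0.0560). Chemoreceptor genes had a peak in 6 of 179 cases (3.35%, Fisher exact adjusted p = 2.46e-27), the strongest at Ir60e (rank 358), Gr93d (rank 800) and Or9a (rank 3283).

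**Figure D2:**
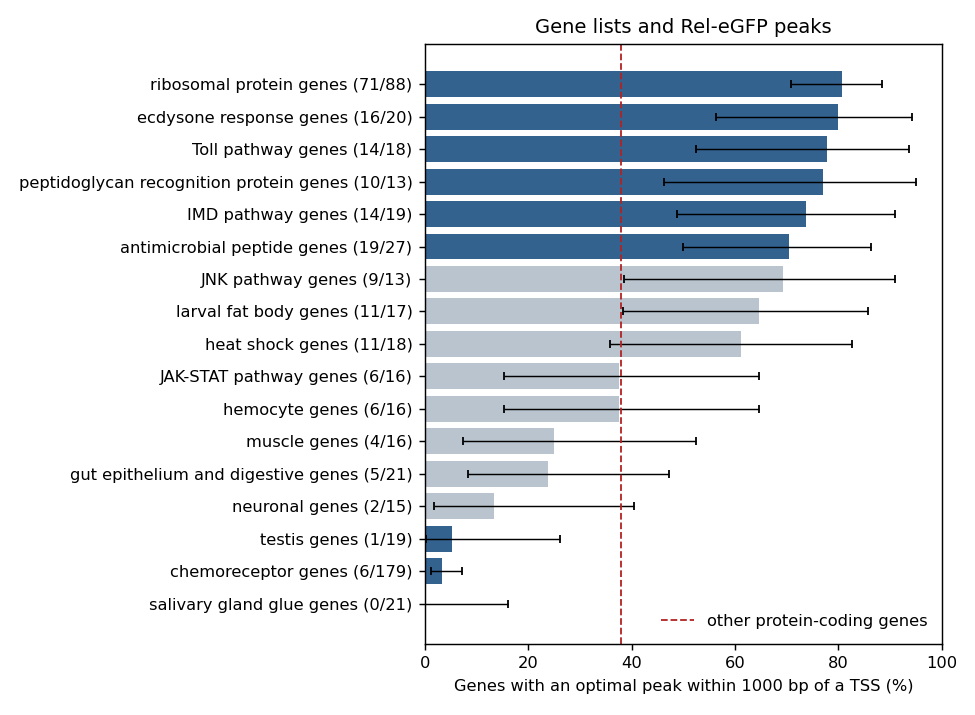
Percent of each list's genes with an optimal peak within 1000 bp of a TSS (x axis), with exact 95% intervals; dark bars passed the Fisher exact test after adjustment, pale bars did not (salivary gland glue genes, at 0, passed), and the dashed line marks other protein-coding genes. Ribosomal protein genes reach 80.7% and chemoreceptor genes 3.35%.

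Sequence at the summits was compared with windows 1000 bp away. The κB consensus was present at 7.86% of summits and 1.33% of flanks, a ratio of 5.89 (exact McNemar adjusted p = 3.91e-106). The ratio was 2.99 for promoter peaks (5.14% against 1.72%) and 11.5 for distal peaks (10.7% against 0.932%). The difference between these ratios was not tested. Motifs of housekeeping promoters were also more frequent at summits, DRE at 3.40% against 0.434% (ratio 7.83, adjusted p = 3.86e-54) and Ohler1 at 2.25% against 0.185% (ratio 12.2, adjusted p = 3.65e-42, exact McNemar), both with ratios above that of κB. GATA (38.9% against 31.5%), GAGA (6.69% against 3.16%), E-box (12.0% against 10.1%), AP-1 (3.11% against 2.22%) and CRE (0.705% against 0.369%) were higher at summits. ETS (0.955% against 1.58%) and Zelda (0.857% against 1.54%) were lower. A second control compared each motif's share at summits with that of the same motif with shuffled columns, at the same summits. It uses no flanks, so it cannot undo a difference between summits and flanks. κB, DRE and Ohler1 passed it and these 7 motifs did not, with AP-1 below its shuffled mean (-0.19 points). GAGA had 34 shuffled orders, too few for its adjusted p to pass. Against shuffled orders the difference was 4.11 points for GAGA (3.53 against flanks), 6.65 for E-box (1.94) and -0.87 for ETS (-0.63). It was 0.34 for CRE (0.34 against flanks) and -0.64 for Zelda (-0.68). The controls differ, so these sizes cannot be set against each other. For GAGA and E-box at least 1 shuffled order reached a higher share than the motif (7.03% and 12.8%).

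**Figure D3:**
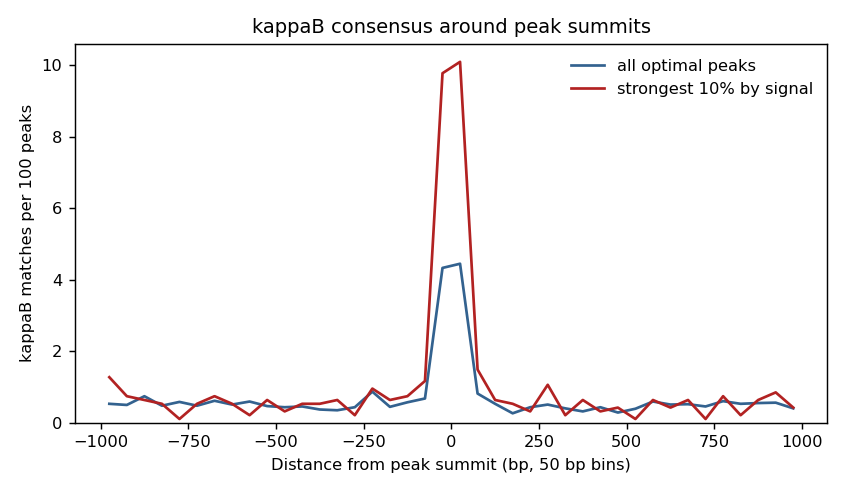
Number of κB matches per 100 peaks (y axis) in 50 bp bins of distance from the summit (x axis, bp), for all optimal peaks and for the strongest 10% by signal. The bins either side of the summit hold 4.33 and 4.45 matches per 100 peaks for all peaks, and 9.78 and 10.1 among the strongest.

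Strong peaks were compared with weak ones. In the top 25% by signal, 12.6% of 2354 peaks had a κB match, against 5.44% of 2354 in the bottom 25% (7.14 points, Fisher exact p = 7.51e-18). Without replicate 2 the difference was 10.9 points (14.4% against 3.53%). The share was 17.1% in the strongest 10% and 5.07% in the weakest 10%. Promoter peaks made up 51.1% of the top 25% and 47.0% of the bottom 25% (Fisher exact p = 0.00613). Without replicate 3 the promoter difference was 2.50 points and did not pass (Fisher exact p = 0.163).

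**Figure D4:**
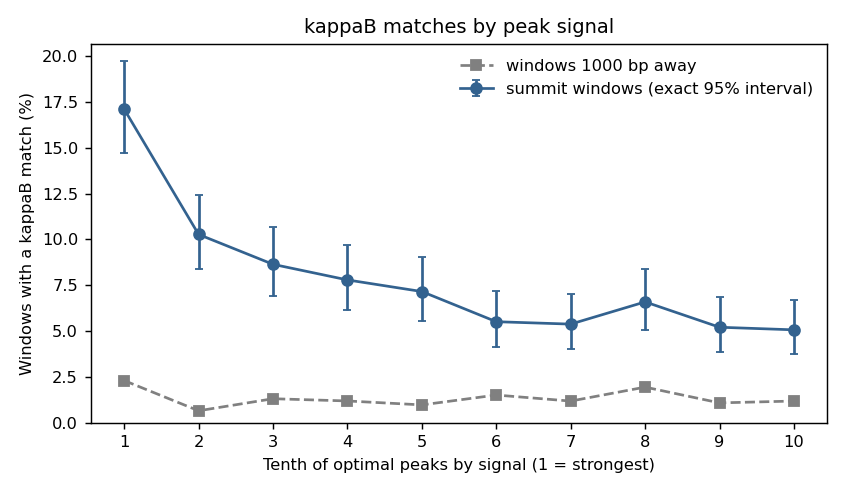
Percent of windows with a κB match (y axis) in 10 equal bins of the optimal peaks ordered by signal (x axis, 1 is the strongest), at summits with exact 95% intervals and in windows 1000 bp away. The strongest bin reaches 17.1% and the weakest 5.07%.

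Peak density on the large chromosome arms ran from 68.0 peaks per Mb on 3R (exact Poisson 95% interval 65.2 to 70.9) to 77.3 on 2R (73.9 to 80.8), with 69.1 on X (65.8 to 72.5). Only X was tested. Chromosome 4, which is largely heterochromatic, had 13 peaks, or 9.64 per Mb (exact Poisson 95% interval 5.13 to 16.5). The X chromosome held 17.3% of the peaks on the large arms and makes up 17.8% of their length (exact binomial p = 0.230). The X share was lower in the top 50% of peaks by signal (-1.39 points, exact binomial p = 0.0124) and without replicate 1 (-1.02 points, exact binomial p = 0.0273), but not without the outer 1 Mb of each arm (-0.064 points, exact binomial p = 0.890).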

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

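Of the tests in this part, those on pooled peaks outside the optimal list and on promoter peaks without a κB match were chosen after the main results were seen. With 3 samples, single samples were not tested as outliers.

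Peaks of the pooled list outside the optimal list, which no comparison above used as a set, still carried κB matches. Among 18835 such summits 3.50% had a match, against 1.43% of windows 1000 bp away, an excess of 2.08 points and a ratio of 2.45 (exact McNemar adjusted p = 5.3e-39). The ratios of DRE (3.35) and Ohler1 (5.10) in the same peaks were higher than that of κB, and both motifs passed. The JNK pathway genes without an optimal peak, grnd, wgn, Traf4 and slpr, all had a weaker pooled peak within 1000 bp of a TSS, 4 of 4 against 25.2% of other genes without an optimal peak. The difference was 74.8 points (Fisher exact adjusted p = 0.0342 over 17 lists), and rests on 4 genes. Of the other lists, chemoreceptor genes passed in the opposite direction (6 of 173, 3.47% against 25.6%, Fisher exact adjusted p = 2e-13).

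The line carries an inserted, tagged copy of Rel, and an extra copy of the region could raise the number of peaks called around Rel. In a window of 43795 bp centred on Rel, the replicate lists held 10, 9 and 8 peaks, against a median of 12 around other protein-coding genes. The highest of the 3 percentiles was 41.1, below the bound of the 95th percentile set beforehand, so no excess of peaks was seen there. A second copy need not add peaks, since peaks were called with a control library, so the count cannot exclude an effect of the copy. Whether signal heights there are changed was not tested.

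Peaks at promoters may come from the general accessibility of active promoters in place of κB sequence, and ribosomal protein genes did have a peak more often. Promoter summits had a κB match 2.99 times as often as their flanks (bootstrap 95% interval 2.39 to 3.85), above the bound of 1.5 set beforehand. This shows that κB sequence was more frequent at promoter summits than 1000 bp away. It cannot exclude accessibility, because motifs of housekeeping promoters passed the same bound over all peaks (DRE 7.83, Ohler1 12.2). A κB match was present at 5.14% of promoter peaks. For promoter peaks without one, a relaxed κB match was 1.52 times as frequent at summits as at flanks (1.34 to 1.72). That interval spans the bound, so accessibility stays open for them as well. No difference between conditions was weighed, since the design has 1 group.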

How the results depend on the processing

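The alternatives of 1 summit per interval, the first gene of each locus and the doubtful testis name were chosen after seeing the data. Of 324 recomputed values, 278 were counted as unchanged. These kept their direction and side of the threshold, lay within 1 SD for the replicate measures, or changed sign where neither value passed. Such changes of sign included digestive genes with loci counted once (-14.1 to 3.72 points), where loci were compared with single genes. By nearest TSS they included JAK-STAT (-0.42 to 15.6) and hemocyte genes (-0.42 to 9.37). Leaving out a replicate could not move the mean replicate overlap by 1 SD, so those values were unchanged by construction and show no stability. Ranking by the authors' −log10 q-value was not run, because the optimal list holds 1 value there. No IDR score was used for ranking. Depth is unknown, so its effect could not be examined. Outside the replicate measures, leaving out a replicate kept the optimal peaks matched in both others, so removal of that replicate was not itself tested. Except where fewer peaks, genes or loci were used by construction, the cause was not tested.

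Replicate overlap was 77.3% with summits within 50 bp, 88.3% within 250 bp, 88.7% by interval overlap, 96.5% with all replicate peaks and 86.3% for the top 50% of each list. Pairwise sharing was 62.1% within 50 bp, 81.5% within 250 bp and 58.5% with all peaks, and 70.9% to 76.4% leaving out each replicate. The correlation was 0.84 as Pearson's r of log2 signal, and 0.70 to 0.83 leaving out each replicate.

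With random lists matched on TSS number, calls ended for peptidoglycan recognition proteins (31.7 points), IMD (25.1) and ecdysone (23.9) genes, and muscle (-31.7) and neuronal (-42.2) genes passed. With TSSs within 500 bp, JNK (35.8), fat body (31.2) and heat shock (27.7) genes passed, and within 5000 bp muscle (-33.3) and neuronal (-31.6) genes. Fat body genes also passed by nearest TSS (36.2), in the top 50% by signal (30.1) and without each replicate (28.0 to 29.1), as did muscle genes in the top 50% (-23.0). Glue genes lost the call with loci counted once and with the first gene of each locus (-38.0 in both), where 0 of 5 loci could not have passed. Peptidoglycan recognition proteins (24.6) and testis genes (-30.3) lost it with the first gene. Both kept it with loci counted once (49.6 and -30.3). There loci were compared with single genes, which raises the share of loci, so the 49.6 points do not show that clustering is without effect.

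Against shuffled columns, a control without flanks, GATA (1.84 points), GAGA (4.11), E-box (6.65), ETS (-0.87), Zelda (-0.64) and CRE (0.34) did not pass, and AP-1 reversed (-0.19). GAGA had too few shuffled orders to pass. Against random windows matched on TSS and GC, each motif kept its direction and passed. With 50 bp either side of the summit the call was lost for AP-1 (0.30), ETS (-0.21) and CRE (0.096). CRE also lost it in the top 50% (0.24) and without replicate 2 (0.23 to 0.33 leaving out each). The κB difference between strong and weak peaks was 7.89 to 10.9 points leaving out each replicate. The promoter difference between strong and weak peaks was 2.50 to 4.62 points leaving out each replicate, and was lost without replicate 3. The X share passed in the top 50% (-1.39) and without replicate 1 (-1.02 to -0.65 leaving out each).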

Other observations

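The tests in this part were all chosen after the main results were seen. Genes of other classes carried peaks less often than protein-coding genes, of which 37.9% had one. A gene with more TSSs has more chances of a peak, and these comparisons were not matched on TSS number. Such matching ended the calls of peptidoglycan recognition protein, IMD and ecdysone genes above, so its part in these gaps is unknown. Of 290 tRNA genes, 88 had a peak within 1000 bp of a TSS (30.3%, Fisher exact adjusted p = 0.0141), and of 269 snoRNA genes 82 did (30.5%, Fisher exact adjusted p = 0.0165). The share was 20.1% for other non-coding RNA genes (655 of 3261, Fisher exact adjusted p = 6.13e-88) and 9.70% for pseudogenes (26 of 268, Fisher exact adjusted p = 8.96e-25). The 32 snRNA genes did not differ past the threshold (28.1%, Fisher exact adjusted p = 0.280).

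Among promoter peaks, those in the strongest and in the weakest 25% of the whole list by signal differed in their motifs. κB was present at 9.90% of 1202 strong promoter summits and 2.53% of 1107 weak ones (Fisher exact adjusted p = 2.59e-13). DRE went the other way, at 3.99% and 7.41% (Fisher exact adjusted p = 0.000602). Ohler1 did not differ past the threshold (3.24% and 3.79%, Fisher exact adjusted p = 0.498).

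A hypothesis is that Rel may also bind κB-like sequence outside the relaxed consensus. The 10 7-mers most enriched at summits on 2L, 2R, X and 4 included AAACCCC, ATTCCCC and AATCCCC, together with CTTATCA and ATCGATA, which resemble GATA and DRE sites. On 3L and 3R, in 2947 pairs without a relaxed κB match, the 7 of them with a run of 4 G or C were 2.72 times as frequent at summits as at flanks (14.6% against 5.36%, bootstrap 95% interval 2.29 to 3.23). Base composition was tested with 200 draws of the same 7-mers with reordered bases, which gave a median ratio of 1.09 and at most 1.82, below the observed ratio. An earlier look at 7-mers had used all arms, so 3L and 3R were not unseen, and binding by another factor with a similar site was not tested.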
